A study of Mus musculus with 6 samples.

How the data were processed

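RNA of mouse platelets, isolated from blood, and of bone marrow cells named megakaryocyte progenitors was measured on 6 Clariom D Mouse arrays. Each cell type had 3 treatments, a PBS control, CTC41-EVs and CTC41.5G-EVs, and each group was 1 array. Per the labels' protocols, the RNA came from cells pooled over the mice of a group. The number of mice per pool, the dose, the route and the time of treatment are not given in the sources used here. Per the labels' protocols, the pools were either used directly or first depleted of leukocytes and erythrocytes with magnetic beads, and which pool had which handling is not given there. The protocols name 3 ng of RNA in one place and 5 ng in another, and they name the mirVana kit in one place and the RNeasy kit in another.

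The deposited values are on a log2 scale, from 0.23 to 14.06 over the 6 arrays. Per the submitters' processing notes, the arrays were summarised with Affymetrix Expression Console 1.4.1.46, while the series description names the MAS5.0 algorithm. The method by which the authors scaled the arrays to each other therefore remained unclear. The genome build of their summary is not stated. The values were used as deposited in the main setting, with no further scaling and no pseudocount, since they were already logarithms. Array signals carry no read depth, and the number of arrays limits the precision.

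Of 72688 probes, 30604 named 1 gene symbol, 2146 named several and 39938 listed none, and only the first kind was used. Of those, 22818 matched the RefSeq gene table of GRCm38.p6 by Entrez identifier, which updated 827 symbols. This left 30142 genes, of which 355 had more than 1 probe and took the probe with the highest mean. Genes named together with another gene on 1 probe, such as the haemoglobin genes and Gp1ba, were left out by this step. Still, 450 genes carried the same values as another gene on all arrays, members of the microRNA list among them. Counts, list tests and percentiles took each of them as a separate gene. Near-identical transcripts, such as those of ribosomal protein genes and their pseudogenes, cannot be assumed to be separated by the probes. The ribosomal protein list, drawn by a symbol pattern, held 3 genes annotated as pseudogenes, Rpl6l, Rps3a2 and Rps3a3.

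Cell type was compared with limma 3.58.1 in R 4.3.3. The model held additive terms for cell type and treatment, with 2 residual degrees of freedom and moderated variances with an intensity trend. Genes entered if their mean over the 6 arrays reached the 50th percentile of all probes, 4.23 on the log2 scale, which left 18875 genes. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05 and at least a 1.5-fold difference. The SD given beside a cell type's mean is over its 3 arrays, which differ in treatment, and the SE is that of the model's difference. Where the mean of 1 cell type lay below 4.23, the size of the difference depends on background, as for Angpt1, Dcn, Rab11a, Ccng1, Rsad2 and Ifit2 in progenitors and Myb and Rpl39l in platelets. For the genes of the rule such differences are also given from the floor. The same model tested EV effects averaged over both cell types. The residual of this model holds array noise together with any treatment effect that differs between the cell types.

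Within a cell type, each EV comparison was 1 array against 1 array, so no test was possible. Genes were counted if they differed by at least 1.5-fold and their mean over the 3 arrays of that cell type reached the 75th percentile of all probes, 5.07 on the log2 scale. Counts over all genes use this threshold. For members of a list and for genes named singly, higher or lower gives the sign alone, and some differ by less than 1.5-fold. The floor holds for the mean over the 3 arrays, so some named genes lie under it on 1 of the arrays compared. The 31 gene lists, of cell type markers, pathways and RNA classes, were fixed before the data were examined, as were the thresholds, the rule for named genes and most alternatives. Lists with at least 5 tested members entered a camera test with a preset correlation of 0.01 and, beside it, with a correlation estimated per list, each adjusted over the 30 fixed lists that entered, and lists added later were adjusted together with these. The list of mitochondrially encoded genes, with 2 genes on the arrays, did not enter. Camera compares a list with the other genes, so its direction can differ from the sign of a list's median. With an estimated correlation it refers its statistic to the 2 residual degrees of freedom, which leaves little room for a small p. The adjusted p rose also where the estimate lay under the preset, as for megakaryocyte transcription factors (-0.008). For ribosomal protein genes the estimate was 0.666, far above it. A high p with an estimated correlation therefore does not show that correlation between genes removed a result, and neither p settles a list. Within a cell type, a list's median difference was set against 10000 random lists of the same size matched on mean signal in 20 bins. The list was described as standing apart at a percentile of at most 1 or at least 99. Of 100 random unchanged lists of 20 genes, 5 reached those percentiles. The random lists hold unrelated genes, whereas members of a list can vary together. Estimated correlations were 0.666 for ribosomal protein, 0.623 for oxidative phosphorylation and 0.45 for immediate early genes. Such lists can reach extreme percentiles on 2 arrays more readily than this check shows. A percentile therefore describes the 2 arrays and is no measure of evidence.

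By the rule for named genes, predicted genes and members of the olfactory, vomeronasal, microRNA, small nucleolar RNA and antigen receptor families were counted but not named. For cell type, the rule took the 10 largest differences each way among called genes with no overlap between the cell types. For each EV comparison with PBS, it took the 8 largest differences each way, and for the EV types against each other the 5 largest each way. For each list described, it took 2 to 4 members with the largest difference in the direction of its median. Protein-coding genes named beside those of the rule were chosen after their values were seen, because pseudogenes and small RNAs filled several of the places.

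On simulated data of the same layout, 96% of genes with a 2-fold cell type difference and 97% of genes with a 2-fold EV effect shared by both cell types were recovered, with 3 and 2 false calls among 18875 genes. The simulated noise was drawn independently from the fitted variances, and no simulated EV effect differed between the cell types. These shares hold for such data only and do not show that shared EV effects are absent where no gene was called. Alternatives were quantile normalization, scaling to the same median, no floor, a floor at the 90th percentile, the mean of a gene's probes, a 2-fold threshold, no treatment term, no intensity trend and leaving out each array in turn. Added after the data were seen were protein-coding genes only, centring on olfactory receptor genes, leaving out ribosomal protein genes and pseudogenes, any EV against PBS within a cell type, differences from the floor, and 6 further lists. Any EV against PBS set both EV arrays of a cell type against its PBS array in limma, where the lone PBS array was assumed to vary like the others. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.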

Results

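Gene expression was measured on 6 arrays, 3 of mouse platelets from blood and 3 of megakaryocyte progenitors from bone marrow. In each cell type, 1 array came from mice given PBS, 1 from mice given CTC41-EVs and 1 from mice given CTC41.5G-EVs, as the labels name them. EVs is the usual abbreviation of extracellular vesicles, membrane particles released by cells. What the 2 line names stand for is not given in the sources used here. Each array held RNA pooled over the mice of a group, so no group had replicates. The median log2 signal over all probes was 4.0, 4.05 and 4.02 on the platelet arrays and 4.38, 4.38 and 4.45 on the progenitor arrays, in the order PBS, CTC41-EVs and CTC41.5G-EVs. Across probes, arrays correlated at 0.961 to 0.967 within platelets, 0.973 to 0.983 within progenitors and 0.823 to 0.838 between the cell types, where probes are not independent replicates.

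The first comparison asked which transcripts distinguished platelets from megakaryocyte progenitors over the 3 treatments. By the rule for named genes, transcripts of known platelet proteins were among the 10 largest differences upwards. Ppbp, a chemokine precursor of platelet granules, stood at 12.43 ± 0.34 (SD, n = 3) in platelets and 5.49 ± 0.33 in progenitors, a log2 difference of 6.94 with SE 0.19 (123-fold). Pf4, platelet factor 4, rose by 6.29 (SE 0.21), Clec1b, the podoplanin receptor CLEC-2, by 6.78 (SE 0.15), and P2ry12, an ADP receptor, by 6.63 (SE 0.13). Rgs18, a regulator of G protein signalling, rose by 6.66 (SE 0.15), and the adhesion receptor gene Cd226 by 6.33 (SE 0.11). The cathepsin inhibitor-like genes Ctla2b and Ctla2a rose by 7.06 (SE 0.19) and 6.42 (SE 0.21), mt-Tk, a mitochondrial lysine tRNA, by 6.75 (SE 0.21), and B2m, the light chain of MHC class I, by 5.86 (SE 0.21). Adjusted p for these 10 genes lay between 1.69e-06 and 2.13e-06. Clec1b, P2ry12, Cd226 and mt-Tk lay below the floor of 4.23 in progenitors, at 3.95, 3.72, 3.04 and 3.58, so the size of their differences depends on background. Measured from the floor they were at least 6.50, 6.12, 5.14 and 6.10.

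By the rule, 6 of the 10 genes furthest below progenitors were genes of granulocyte granules. Ngp, neutrophilic granule protein, stood at 4.89 ± 0.44 (SD, n = 3) in platelets and 8.76 ± 0.15 in progenitors, a log2 difference of -3.87 with SE 0.17 (adjusted p = 4.02e-06). Mpo, myeloperoxidase, differed by -3.20 (SE 0.15), Elane, neutrophil elastase, by -2.97 (SE 0.13), and Camp, cathelicidin, by -2.76 (SE 0.15). The basophil protease Mcpt8 differed by -2.59 (SE 0.11) and the mast cell and basophil protease Prss34 by -2.57 (SE 0.15). The other genes under the rule were Rnu2-10, a U2 spliceosomal RNA (-2.71, SE 0.16), the pseudogene Speer8-ps1 (-2.68, SE 0.12), Gpr31b (-2.57, SE 0.17) and Prr23a3 (-2.39, SE 0.22). The highest adjusted p among these 10 genes was 9.2e-05, for Prr23a3. Elane, Mcpt8 and Prr23a3 lay below the floor in platelets, at 4.19, 3.99 and 3.67, and measured from the floor they differed by -2.93, -2.35 and -1.83.

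The lists of platelet function rose in platelets as groups. Of 24 tested platelet receptor and adhesion genes, 21 rose, 21 also when adjusted over the list alone, with a median of 3.04 (adjusted p = 1.13e-13). With an estimated correlation, tested here and below on 2 degrees of freedom, the adjusted p was 0.413. The largest members were Clec1b, P2ry12 and Cd226, and Cd9, a tetraspanin, rose by 4.91 (SE 0.15). Of 18 alpha-granule and cargo genes, 13 rose, 13 adjusted over the list alone, with a median of 2.73 (adjusted p = 2.26e-08, and adjusted p = 0.45 with an estimated correlation). Beside Ppbp and Pf4, coagulation factor F5 rose by 5.17 (SE 0.13) and clusterin, Clu, by 4.73 (SE 0.16). Of 26 cytoskeleton and signalling genes, 24 rose, 24 adjusted over the list alone, with a median of 2.59 (adjusted p = 1e-15, and adjusted p = 0.413 with an estimated correlation). The G protein subunit Gng11 rose by 5.65 (SE 0.15), the myosin light chain Myl9 by 5.43 (SE 0.16) and the small GTPase Rap1b by 5.12 (SE 0.19).

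Of 14 megakaryocyte transcription factor genes, 7 rose in platelets and 7 did not pass, with 7 adjusted over the list alone and a median of 0.46 (adjusted p = 0.000412, and adjusted p = 0.413 with an estimated correlation). Fli1 rose by 2.56 (SE 0.17), Nfe2 by 2.16 (SE 0.09), Mef2c by 2.10 (SE 0.10) and Gfi1b by 1.33 (SE 0.15), whereas Gata1 and Gata2 differed by -0.01 (SE 0.09) and -0.17 (SE 0.12) and were not called. Markers of other blood cells moved with the cell type too. On the progenitor arrays Ngp, Camp and Mpo stood at 8.76, 8.66 and 8.12, and Pf4 and Ppbp at 6.44 and 5.49. Other cells in the pools of either kind cannot be told apart from the named cell types, since the handling of each pool is not given. Of 17 erythroid genes, 7 rose in platelets, 7 adjusted over the list alone, with a median of 0.38 (adjusted p = 0.000802, and adjusted p = 0.468 with an estimated correlation). They included the haem synthesis genes Fech (4.86, SE 0.16) and Alas2 (4.76, SE 0.14) and the mitochondrial iron importer Slc25a37 (2.95, SE 0.14). Of 21 neutrophil genes, 14 fell in platelets, 14 adjusted over the list alone, with a median of -0.97 (adjusted p = 0.0126, and adjusted p = 0.413 with an estimated correlation).

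**Figure D1:**
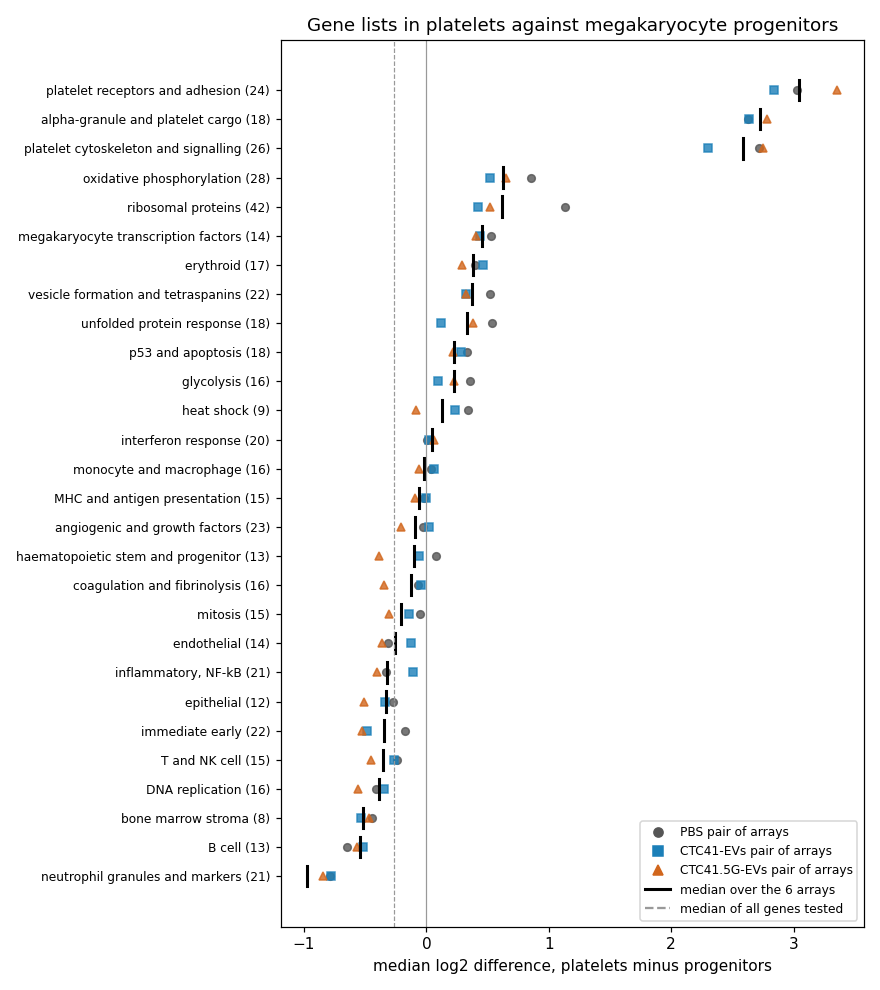
Median log2 difference of platelets minus progenitors (horizontal axis) for the tested fixed gene lists, with the number of tested genes in brackets; points give the difference within the PBS, CTC41-EVs and CTC41.5G-EVs pairs of arrays, and the black bar the median over the 6 arrays. The microRNA and small nucleolar RNA lists are not drawn. The 3 lists of platelet function stand at 2.59 to 3.04, the neutrophil list at -0.97, and the dashed line marks the median of all genes tested at -0.26.

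Energy metabolism and translation genes also rose in platelets. Of 28 oxidative phosphorylation genes, 16 rose, 16 adjusted over the list alone, with a median of 0.63 (adjusted p = 5.57e-07, and adjusted p = 0.56 with an estimated correlation). The respiratory chain genes Cox5a, Ndufa1 and Ndufa4 rose by 5.23 (SE 0.18), 4.90 (SE 0.17) and 4.01 (SE 0.17). Of 42 cytosolic ribosomal protein genes, 22 rose and 2 fell, the same numbers adjusted over the list alone, with a median of 0.62 (adjusted p = 6.43e-07, and adjusted p = 0.591 with an estimated correlation). Rpl41 rose by 3.31 (SE 0.26) and Rpl38 by 2.04 (SE 0.20), and the 2 that fell were Rpl6l, annotated as a pseudogene (-1.58, SE 0.15), and the paralog Rpl39l (-1.01, SE 0.09). Of 16 glycolysis genes, 6 rose, 6 adjusted over the list alone, with a median of 0.22 (adjusted p = 0.0233, and adjusted p = 0.413 with an estimated correlation), led by the glucose transporter Slc2a3 (3.52, SE 0.16) and Tpi1 (1.71, SE 0.16).

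Genes of vesicle formation and tetraspanins rose in 10 of 22 cases, 10 adjusted over the list alone, with a median of 0.37 (adjusted p = 1.96e-05, and adjusted p = 0.413 with an estimated correlation). The recycling GTPase Rab11a rose by 3.89 (SE 0.12), syntenin, Sdcbp, by 3.52 (SE 0.15) and the tetraspanin Cd81 by 2.98 (SE 0.15). Of 18 unfolded protein response genes, 6 rose and 2 fell, the same numbers adjusted over the list alone, with a median of 0.33 (adjusted p = 0.00335, and adjusted p = 0.56 with an estimated correlation). Edem1 rose by 3.88 (SE 0.18) and Ddit3 by 2.20 (SE 0.12). Of 18 p53 and apoptosis genes, 6 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 0.22 (adjusted p = 0.00528, and adjusted p = 0.413 with an estimated correlation). Ccng1 rose by 3.20 (SE 0.11) and the survival gene Bcl2l1 by 1.61 (SE 0.11), while the death receptor gene Fas fell by 2.27 (SE 0.23).

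Of 279 microRNA genes, 164 were called lower and 13 higher in platelets, the same numbers adjusted over the list alone, with a median of -0.76 (adjusted p = 1.96e-05, and adjusted p = 0.503 with an estimated correlation). With arrays centred on olfactory receptor genes the median of the microRNA list was -0.04. Of its tested members, 43 lay below the floor in platelets and 2 in progenitors. Olfactory and type 1 vomeronasal receptor genes, lists added after the data were seen, had medians of -1.12 and -2.60 in the same direction. Without a floor, over members not named as pseudogenes, these were -0.65 and -0.72. Of 30 small nucleolar RNA genes, 16 were called lower, 16 adjusted over the list alone, with a median of -0.63 (adjusted p = 0.0254, and adjusted p = 0.413 with an estimated correlation), and this median changed sign, to 0.09, with arrays centred on olfactory receptor genes.

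The other lists did not pass the list test for cell type in the main setting, while single members did. Of 13 stem and progenitor genes (adjusted p = 0.764), the receptor kinase Kit fell by 1.39 (SE 0.09) and the transcription factor Myb by 0.93 (SE 0.09), while Slamf1, also a marker of megakaryocyte progenitors, and Adgrg1 rose by 4.94 (SE 0.14) and 1.96 (SE 0.18). Of 13 B cell genes, 5 fell, 5 adjusted over the list alone, among them Vpreb2 (-1.53, SE 0.11), and the list's adjusted p was 0.0676. Of 20 interferon response genes, 5 rose, 5 adjusted over the list alone, led by Rsad2 (3.70, SE 0.18) and Ifit2 (2.83, SE 0.13), and the list's adjusted p was 0.0575. Of 16 monocyte and macrophage genes, lysozyme, Lyz2 (2.94, SE 0.17), was the 1 called (adjusted p = 0.202 for the list). Of 22 immediate early genes, 6 fell and 1 rose, the same numbers adjusted over the list alone, and Fosb fell by 2.36 (SE 0.22; adjusted p = 0.487 for the list).

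The adjusted p of the remaining lists was 0.0572 for heat shock, 0.123 for DNA replication, 0.262 for epithelial genes, 0.262 for coagulation, 0.282 for T and NK cells, 0.352 for angiogenic factors, 0.453 for antigen presentation, 0.487 for bone marrow stroma, 0.548 for inflammatory cytokines, 0.631 for mitosis and 0.835 for endothelial genes. Among their members, the matrix gene Dcn rose by 4.09 (SE 0.14), Angpt1, a ligand of the receptor Tek, by 4.86 (SE 0.12), and Anxa5, which binds phosphatidylserine, by 2.36 (SE 0.16). The median was below 0 and the mean and the test pointed up for 6 lists, stem and progenitor, monocyte, mitosis, coagulation, angiogenic factors and antigen presentation. For stroma the median of -0.52 and the mean of 0.00 differed while the test pointed down.

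Over all 18875 genes, limma called 3063 genes higher and 4854 lower in platelets. Of all genes tested, 14804 showed no overlap between the cell types, where chance gives 10% for 3 arrays against 3. The balance of directions depended on scaling. The median of all genes was -0.26 as deposited, 0.05 after quantile normalization and 0.46 with arrays centred on olfactory receptor genes, and the number called lower was 2282 and 1033 in the latter 2 settings. With the floor at the 90th percentile the lists of megakaryocyte transcription factors (adjusted p = 0.275), glycolysis (0.145) and ribosomal proteins (0.088) no longer passed, although their medians were higher, at 0.73, 0.88 and 0.95. Without a floor small nucleolar RNAs did not (median -0.29, adjusted p = 0.239), and after quantile normalization interferon response (0.0204) and heat shock (0.0334) passed. These 2 lists also passed with arrays scaled to the same median (0.026 and 0.0409), without a floor (0.0238 and 0.00277) and when 1 array was left out, either CTC41-EVs array for interferon response (0.0409 to 0.0418) and either CTC41.5G-EVs array for heat shock (0.0293). Interferon response also passed with arrays centred on olfactory receptor genes (0.0283). B cell genes passed with protein-coding genes only (0.0206) and with arrays scaled to the same median (0.05), and monocyte genes without a floor (0.0462).

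The next comparison tested the shift with EVs averaged over both cell types. limma called 0 genes for CTC41-EVs, 0 for CTC41.5G-EVs and 0 between the EV types, with 577, 1171 and 1157 genes at an unadjusted p under 0.05, where chance gives 944. The smallest adjusted p was 0.596, 0.512 and 0.61. In the list test with the preset correlation, cytoskeleton and signalling genes stood above other genes with CTC41.5G-EVs (median 0.22, adjusted p = 0.0397, and adjusted p = 0.861 with an estimated correlation). So did stem and progenitor genes (median 0.21, adjusted p = 0.0461, and adjusted p = 0.861 with an estimated correlation), while microRNA genes stood below them with a median of 0.03 and a mean of -0.01 (adjusted p = 0.0397, and adjusted p = 0.861 with an estimated correlation). Between the EV types, CTC41.5G-EVs stood above CTC41-EVs for platelet receptor genes (median 0.28, adjusted p = 0.00367), cytoskeleton and signalling genes (0.24, adjusted p = 0.000986) and ribosomal protein genes (0.23, adjusted p = 0.0313). With an estimated correlation the adjusted p was 0.976 for each. Adjusted over the list alone, 0 members of these 5 lists passed. No fixed list passed for CTC41-EVs. This test takes the mean over both cell types, and a list can pass it from 1 of them. With CTC41.5G-EVs the cytoskeleton list had medians of 0.27 in platelets (percentile 99.98 of matched lists) and 0.11 in progenitors (percentile 38.8). The stem and progenitor list had 0.17 (percentile 92.93) and 0.31 (percentile 98.27), and the microRNA list -0.03 (percentile 1.98) and 0.02 (percentile 0). Between the EV types the medians in platelets and progenitors were 0.47 (percentile 99.95) and 0.12 (percentile 78.02) for receptor genes, 0.37 (percentile 96.32) and 0.05 (percentile 22.01) for cytoskeleton genes and 0.27 (percentile 91.46) and 0.18 (percentile 99.16) for ribosomal protein genes.

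In platelets, CTC41-EVs went with lower signals of ribosomal protein and oxidative phosphorylation genes than PBS. Genes of like signal tended lower too. Matched random lists ran from -0.254 to -0.022 (1st to 99th percentile) for the first list and from -0.22 to 0.033 for the second. Of 37 ribosomal protein genes, 32 were lower and 5 higher on the array, of which 6 and 0 by at least 1.5-fold. Their median was -0.28 (percentile 0.14 of matched random lists). Rpl4 differed by -0.74, Rps3a2, a pseudogene by its annotation that the list's symbol pattern took in, by -0.66 and Rpl8 by -0.63. Of 25 oxidative phosphorylation genes, 23 were lower, with a median of -0.27 (percentile 0.06), led by cytochrome c, Cycs (-0.84), and Uqcrb (-0.81). The 150 microRNA genes stood above matched lists with a median of 0.03 (percentile 100), but with the floor at the 90th percentile the median was -0.09 and the list did not stand apart (percentile 91.92).

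Single genes higher with CTC41-EVs in platelets were Rn7s1 and Rn7s2, the RNA of the signal recognition particle, which share 1 set of values (1.10), the lung surfactant gene Sftpc (1.04), mt-Rnr1, a mitochondrial ribosomal RNA (0.92), Mphosph6 (0.80), Ctla2a (0.80), Bloc1s3, a gene of lysosome-related organelle biogenesis (0.79), and the 5S rRNA gene n-R5s28 (0.67). Genes lower were the Astx transcripts Astx1a, Astx1b and Astx1c, with 1 set of values (-1.28), Astx6 (-1.24) and Astx3 (-1.13), Bcl2a1a, a survival gene (-1.22), mt-Tk (-0.94) and the galectin gene Lgals1 (-0.92). In all, 37 genes were at least 1.5-fold higher and 193 lower among 8247, of which 7 and 67 were protein-coding, and 91 of the lower ones were pseudogenes. After quantile normalization the value of mt-Rnr1 turned to -0.07 and that of Rn7s1 and Rn7s2 fell to 0.14, and the oxidative phosphorylation list no longer stood apart with the floor at the 90th percentile (median -0.25, percentile 4.9). Without a floor, unfolded protein response genes (median -0.19, percentile 0.55) and heat shock genes (median -0.24, percentile 0.19) also stood below matched lists.

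CTC41.5G-EVs in platelets went with higher signals of platelet genes. Genes of like signal tended higher too. Matched random lists ran from -0.088 to 0.282 (1st to 99th percentile) for alpha-granule and cargo genes. They ran from -0.058 to 0.218 for cytoskeleton and signalling genes and from -0.055 to 0.241 for receptor and adhesion genes. Of 15 alpha-granule and cargo genes, 13 were higher than with PBS, with a median of 0.39 (percentile 99.99). Pf4 was higher by 0.69, Ppbp by 0.67, Tgfb1 by 0.59 and Clu by 0.54. Of 26 cytoskeleton and signalling genes, 25 were higher, with a median of 0.27 (percentile 99.98), led by the adaptor Lat (0.47), the actin crosslinker Actn1 (0.45) and the integrin activator Fermt3 (0.44). All 23 receptor and adhesion genes were higher, with a median of 0.24 that did not stand apart (percentile 98.8), and neutrophil genes had a median of 0.18 (percentile 98.98). Without a floor both lists stood apart, at medians of 0.24 (24 of 24 higher, percentile 99.67) and 0.11 (percentile 99.25), and ribosomal protein genes stood below matched lists (median -0.07, percentile 0.66).

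Single genes higher with CTC41.5G-EVs in platelets were Sftpc (1.67), Scgb1a1, the club cell secretory protein (1.08), Rn7s1 and Rn7s2 (0.95), the ferritin heavy chain Fth1 (0.88), the cytokine gene Mif (0.82), the mitochondrial peroxidase Prdx3 (0.75) and the interferon-inducible GTPase Irgm2 (0.73). Genes lower were Prg4, lubricin (-1.05), the lipoxygenase Alox15 (-0.97), Igfbp5 (-0.88), the antiviral gene Rsad2 (-0.85), Hnrnpa1l2-ps (-0.85), Dcaf13 (-0.81), Atp5mpl (-0.80) and Rpl27a-ps2 (-0.79). In all, 53 genes were at least 1.5-fold higher and 108 lower among 8247, of which 22 and 28 were protein-coding. With protein-coding genes only, the cytoskeleton list fell short of standing apart with its median unchanged at 0.27 (percentile 98.11), and Rn7s1 and Rn7s2 were at 0.02 after quantile normalization.

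**Figure D2:**
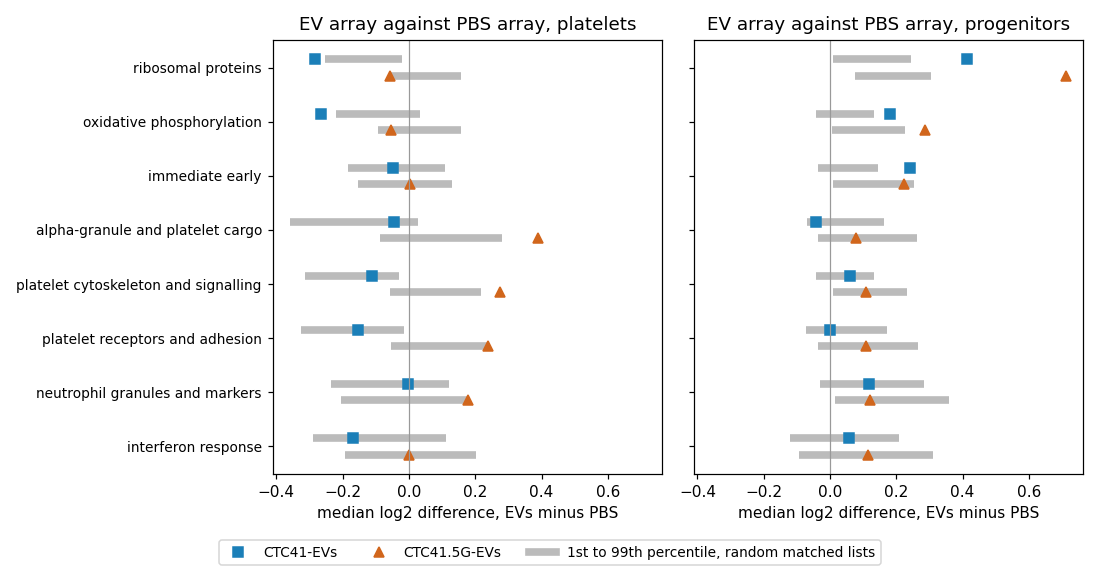
Median log2 difference of each EV array minus the PBS array (horizontal axis) for 8 gene lists in platelets (left) and progenitors (right); grey bars span the 1st to the 99th percentile of random lists matched on signal. Ribosomal protein genes lie at -0.28 with CTC41-EVs in platelets and at 0.41 and 0.71 with CTC41-EVs and CTC41.5G-EVs in progenitors.

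Between the EV types in platelets, platelet receptor genes were higher with CTC41.5G-EVs in 21 of 23 cases, with a median of 0.47 (percentile 99.95). Genes of like signal were higher too, with matched random lists running from 0.151 to 0.423 (1st to 99th percentile). Alpha-granule and cargo genes, with a median of 0.305 (percentile 54.57), and cytoskeleton and signalling genes, with 0.37 (percentile 96.32), did not stand apart. The integrin subunit Itgb3 was higher by 0.75, Gp5 by 0.69, F2rl2 by 0.61 and Gp9 by 0.60. The 150 microRNA genes stood below matched lists, with a median of -0.10 (percentile 0). By the rule, Astx6 (1.55), Astx1a, Astx1b and Astx1c (1.21) and the transcript Orly (1.03) were higher, and Prg4 (-0.90), n-R5s41 (-0.89), Mphosph6 (-0.76), Llph-ps1 (-0.74) and Lypd3 (-0.73) were lower. In all, 230 genes were at least 1.5-fold higher and 73 lower, of which 139 and 11 were protein-coding. With protein-coding genes only, the receptor list did not stand apart with its median unchanged at 0.47 (percentile 96.2), and after quantile normalization 86 genes were higher.

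In progenitors, CTC41-EVs went with higher signals of ribosomal protein, respiration and immediate early genes than PBS. Of 34 ribosomal protein genes, 31 were higher, 10 of them at least 1.5-fold, with a median of 0.41 (percentile 100), among them Rpl35 (0.91), Rps3a3, annotated as a pseudogene (0.89), Rpl8 (0.82) and Rpl4 (0.77). Of 20 oxidative phosphorylation genes, 19 were higher, with a median of 0.18 (percentile 99.96), led by Ndufa4 (0.53) and Uqcrb (0.38). Of 18 immediate early genes, 17 were higher, with a median of 0.24 (percentile 99.99), led by the phosphatase Dusp1 (0.74), Fosb (0.65) and Jun (0.48). Stem and progenitor genes had a median of 0.24 over 7 genes (percentile 99.17), with Adgrg1 at 0.43 and Kit at 0.27. B cell genes had a median of -0.12 over 9 genes (percentile 0.22), with Vpreb3 at -0.34, and the 220 microRNA genes one of -0.04 (percentile 0).

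By the rule, the genes most above PBS with CTC41-EVs in progenitors were pseudogenes of ribosomal proteins, Rpl30-ps2 (1.06), Rps6-ps4 (1.05), Rpl31-ps8 (1.03), Rps23-ps (1.01), Rpl3-ps2 (1.01), Rps12-ps23 (0.995), Rps12-ps22 (0.97) and Rps12-ps20 (0.96). The largest protein-coding genes beside the ribosomal ones were Pabpc1, the cytoplasmic poly(A)-binding protein (0.89), Hnrnpa3 (0.85), Serinc3 (0.83) and Lrrc32 (0.81). Genes lower were the glycolytic gene Pgk1 (-0.66), Foxs1 (-0.62), the DNA repair gene Mgmt (-0.55), Tssk3 (-0.55), Trim56 (-0.53), Tmem151b (-0.53), Fth1 (-0.51) and Psors1c2 (-0.51). Of these, only Pgk1 and Foxs1 reached 1.5-fold. In all, 336 genes were at least 1.5-fold higher and 11 lower among 10858, of which 59 and 2 were protein-coding and 188 of the higher ones pseudogenes. With the floor at the 90th percentile the oxidative phosphorylation and immediate early lists did not stand apart (medians 0.20 and 0.34, percentiles 93.35 and 96.03). The stem and progenitor list did not stand apart after quantile normalization (median 0.23, percentile 97.76), with arrays scaled to the same median (0.15, percentile 94.35) or centred on olfactory receptor genes (0.26, percentile 97.34), nor without a floor (median 0.11, percentile 96.53), where the B cell list did not either (median -0.06, percentile 3.25) and DNA replication (median 0.09, percentile 99.29) and small nucleolar RNA genes (median 0.06, percentile 99.17) did.

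CTC41.5G-EVs in progenitors went with higher signals of the same 2 groups, ribosomal protein and respiration genes. Of 34 ribosomal protein genes, 32 were higher, 19 of them at least 1.5-fold, with a median of 0.71 (percentile 100), led by Rpl35 (1.45), the annotated pseudogene Rps3a3 (1.29) and Rpl41 (1.02). Of 20 oxidative phosphorylation genes, 19 were higher, with a median of 0.29 (percentile 99.98), led by Uqcrq (0.81) and Ndufa1 (0.55). Of 10 DNA replication genes, 9 were higher, with a median of 0.26 (percentile 99.08), with the sliding clamp Pcna at 0.38 and the helicase subunit Mcm5 at 0.31. Immediate early genes had a median of 0.22 that did not stand apart (percentile 96.81), with Dusp1 at 1.21, Fosb at 1.04, Jun at 0.67 and Egr1 at 0.64. The 220 microRNA genes stood below matched lists (percentile 0) with a median of 0.02, which was -0.15 after quantile normalization. On the same array type 1 vomeronasal receptor genes, a list added after the data were seen, had a median of -0.13 over 48 genes (percentile 0). Olfactory receptor genes were not lower there, with a median signal over 277 tested genes of 5.33 and 5.18 with PBS. The median of all genes tested was higher there too, at 5.245 against 5.148 with PBS.

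By the rule, the genes most above PBS with CTC41.5G-EVs in progenitors were Rpl35, Ubb-ps (1.43), Rpsa-ps2 (1.38), Tpt1-ps3 (1.31), Rps3a3, Rpl31-ps8 (1.24), Rpl10a-ps1 (1.22) and Dusp1. Other protein-coding genes were Pabpc1 (1.13), the thioredoxin inhibitor Txnip (1.07), Ctla2a (1.04) and Fas (1.02). Genes lower were Atp5l2 (-1.22), the histone gene H2al1k (-0.82), the 14-3-3 gene Ywhah (-0.75), Inmt (-0.72), Llph-ps1 (-0.70), Mettl7a3 (-0.66), the ephrin receptor Ephb1 (-0.63) and n-R5s152 (-0.63). In all, 594 genes were at least 1.5-fold higher and 81 lower among 10858, of which 164 and 20 were protein-coding and 307 and 33 pseudogenes. After quantile normalization 293 were higher and 181 lower, Rpl10a-ps1 was at 0.65, and the DNA replication list did not stand apart (median 0.13, percentile 92.84), as with arrays scaled to the same median (0.13, percentile 95.45) and the mean of the probes (0.26, percentile 98.85), nor did oxidative phosphorylation with the floor at the 90th percentile (median 0.23, percentile 88.83), while Ephb1 was at -0.25 with the mean of its probes. Without a floor the stem and progenitor list stood apart (14 of 14 higher, median 0.26, percentile 99.67).

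**Figure D3:**
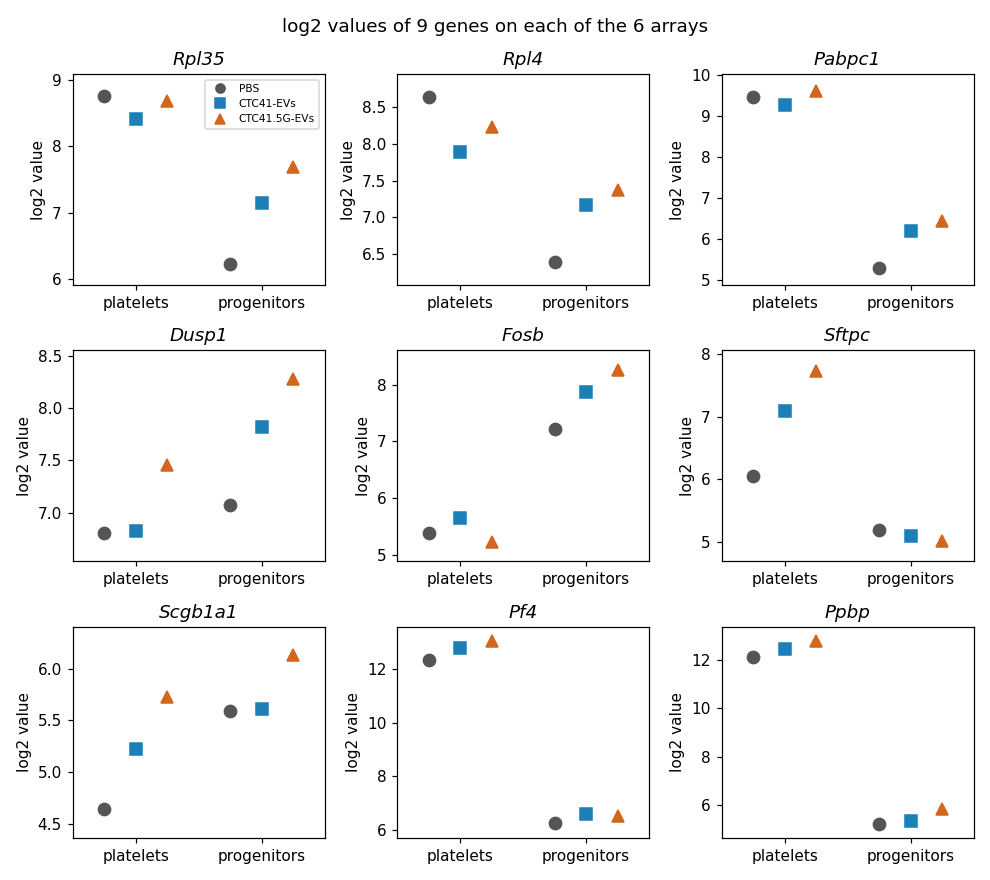
log2 values (vertical axes, which differ between panels and do not start at 0) of 9 genes on each of the 6 arrays, with 1 point per array in the order PBS, CTC41-EVs and CTC41.5G-EVs. In progenitors Rpl35 stands at 6.23, 7.14 and 7.68, and in platelets Sftpc stands at 6.05, 7.09 and 7.72.

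Between the EV types in progenitors, ribosomal protein genes were higher with CTC41.5G-EVs in 30 of 34 cases, with a median of 0.18 (percentile 99.16) and Rps15 at 0.69. By the rule, the genes furthest above were Slc35e4 (0.90), Sms-ps (0.84), Rpsa-ps2 (0.82), the vasopressin gene Avp (0.82) and Rpl10a-ps1 (0.80), and those furthest below were Atp5l2 (-1.21), Ephb1 (-0.85), Rpl35a-ps5 (-0.84), Hmga2-ps1 (-0.81) and Mrgpra2b (-0.79). In all, 66 genes were at least 1.5-fold higher and 85 lower, with 20 protein-coding genes each way. The ribosomal protein list did not stand apart after quantile normalization (median 0.13, percentile 98.81), with the floor at the 90th percentile (0.21, percentile 98.99), with the mean of the probes (0.16, percentile 98) or with protein-coding genes only (0.16, percentile 96.9), and Ephb1 was at -0.43 with the mean of its probes.

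The differences of an EV array from PBS were then set side by side in the 2 cell types, which share no array, over 6473 genes past both floors. For CTC41-EVs, 1 gene was at least 1.5-fold higher in both, Ctla2a, by 0.80 in platelets and 0.69 in progenitors, where independence gives 1.21, and 0 genes were lower in both. In opposite directions were 48 genes, where independence gives 5.06, among them Rpl4, Rpl8, Rps3a1, Hnrnpa3, Ssr2 and the transcripts Astx1a, Astx1b, Astx1c and Astx6. Most of the others were pseudogenes, many of ribosomal proteins, or predicted genes. Probes may not separate these, and Astx1a, Astx1b and Astx1c have 1 set of values. The 48 are therefore not independent genes, and the excess over 5.06 is no test. For CTC41.5G-EVs, 12 genes were higher in both, where independence gives 3.59, among them Mif (0.82 and 0.91), Dusp1 (0.65 and 1.21), Ppbp (0.67 and 0.62) and Eif1-ps3. Llph-ps1 was the 1 gene lower in both, and 6 genes went in opposite directions, where independence gives 5.32, among them the copper chaperone Atox1 and Tspyl3. Across genes, which are not independent replicates, Pearson's r was -0.326 for CTC41-EVs and 0.076 for CTC41.5G-EVs, and Spearman's rho -0.272 and 0.068.

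The 2 EV types share 1 PBS array within a cell type, so part of any likeness comes from that array. In progenitors, 189 genes were higher with both EV types, where independence gives 18 and a simulation of unchanged groups against the shared array gave 18.1. None were lower with both, where independence gives 0.0751 and the simulation gave 17.6. The simulated arrays had 79.4 genes higher and 78.4 lower than PBS, against 336 and 594 higher and 11 and 81 lower on the real ones. Pearson's r across genes was 0.626, against 0.5 in the simulation, and the covariance 0.0335 against 0.0224. In platelets, 9 genes were higher with both EV types, where independence gives 0.238 and the simulation gave 16.9, and 35 lower, where these were 2.53 and 16.3. The simulated arrays had 72.3 higher and 73.1 lower, against 37 and 53 higher and 193 and 108 lower on the real ones. Pearson's r was 0.378, against 0.499 simulated, and the covariance 0.0201 against 0.0245. A PBS array that stands apart in these genes gives such counts by itself. With 1 PBS array per cell type the control could not be split, so the counts do not measure a likeness of the EV types beyond it.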

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

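Chosen only after the results were seen were the comparisons of any EV with PBS, the test of probes with no gene symbol, the test of scaling for the silent receptor families and the values without a floor for the lung genes. The first set the mean of both EV arrays of a cell type against its PBS array and tested in limma whether that difference itself differed between platelets and progenitors.

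The 2 residual degrees of freedom of this model come from the EV arrays alone, and each lone PBS array was assumed to vary like them. The p-values therefore hold no spread of the PBS pools, and no difference of EV effects between the cell types is concluded from them. Of the fixed lists, 5 were flagged under the preset correlation, given as the median log2 effect in platelets minus that in progenitors. Among lists added later, described below, ribosomal protein pseudogenes differed by -0.677, translation factor genes by -0.344 and lung epithelium genes by 0.207. The 5 fixed lists follow. Ribosomal protein genes differed by -0.591 (adjusted p = 6.81e-12), oxidative phosphorylation genes by -0.443 (adjusted p = 5.54e-05) and immediate early genes by -0.252 (adjusted p = 0.0022). Alpha-granule and cargo genes differed by 0.107 (adjusted p = 0.0261) and microRNA genes by 0.042 (adjusted p = 0.000355). With an estimated correlation the adjusted p was 0.972 for each of the 5. No single gene passed this test in limma, with 1009 of 18875 genes at an unadjusted p under 0.05, where chance gives 944, and a smallest adjusted p of 0.251.

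Among probes with no gene symbol, which the comparisons did not use, 23 of 6013 were at least 2-fold above PBS on both EV arrays in platelets and 16 were at least 2-fold below. In progenitors 18 of 9337 were above and 8 below. Both differences contain the 1 PBS array of the cell type. With both EV arrays set against PBS in limma, 0 of 15622 such probes were called in either cell type, with 693 in platelets and 672 in progenitors at an unadjusted p under 0.05, where chance gives 781.

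Ribosomal protein genes were higher on both EV arrays of progenitors, with medians of 0.41 and 0.71. A scaling difference common to genes of like signal moves the matched random lists as well, so it cancels in the percentiles. These were 100 on both arrays as deposited and 99.99 and 100 after quantile normalization, so normalization added no separate test. Ribosomal protein genes thus rose beyond genes of like signal, which such scaling alone does not give. How much of these medians came from scaling was not tested. A lack of neutrophils in the EV pools is argued against, since the neutrophil list stood at percentiles 22.84 and 64.6, not at the bottom. More short transcripts in the EV samples cannot be told apart from a change in these genes. The oxidative phosphorylation list, mostly short transcripts, had 0.439 and 0.402 of the ribosomal protein median, with bootstrap intervals of 0.22 to 1.021 and 0.261 to 0.688 that hold the bound of 0.5. The treatment stays open as well, untested, because each group was 1 pool whose handling may have differed.

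Sftpc and Scgb1a1, genes of lung epithelium, were higher on both EV arrays of platelets, with Sftpc at 6.05, 7.09 and 7.72 and Scgb1a1 at 4.64, 5.22 and 5.73 for PBS, CTC41-EVs and CTC41.5G-EVs. A candidate source is lung RNA in blood drawn by cardiac puncture, and per the labels' protocols platelets were isolated by centrifugation, and which pools were then depleted of leukocytes and erythrocytes with beads is not given in the sources used here. The other lung genes above the floor, 5 in number, had medians at percentiles 63.15 and 81.92, whereas all 19 others without a floor had medians of 0.17 and 0.17 at percentiles 99.85 and 99.93, so the 2 readings differ and lung RNA cannot be told apart from other sources. The abundant lung transcript Sftpb stood at 5.17, 5.36 and 5.41, and Scgb1a1 stood at 5.59, 5.61 and 6.13 in progenitors, where the same 19 genes had percentiles of 28.28 and 19.43. An effect of EVs on these genes in platelets stays open, untested.

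Olfactory and type 1 vomeronasal receptor genes, silent in blood cells as far as is known, were lower in platelets than in progenitors. A scaling difference between arrays is argued against as the whole cause, since relative to all genes tested the vomeronasal family shifted by -2.339 and the olfactory family by -0.857. Those values cover the 51 and 277 members past the floor. Of these, 41 and 168 lay below it in platelets and 0 in progenitors, so this selection favours lower values in platelets. Without a floor the shifts of 183 and 1084 members not named as pseudogenes were -0.474 (bootstrap interval -0.74 to -0.315) and -0.409 (-0.461 to -0.368), and after quantile normalization -0.56 and -0.446. Genomic DNA or RNA of nuclei in the progenitor samples predicted a shift beyond -0.3 in 3 further silent families, and keratin-associated protein genes shifted by -0.42 and beta-defensin genes by -0.339, but taste receptor genes by -0.062 (bootstrap interval -0.487 to 0.157). That source therefore cannot be told apart from others on these families, and the cell type itself stays open.

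The cell type difference rested on 3 arrays against 3, which allow 10 splits. Only 1 of the 10 splits, the real one, gave as many as 7917 called genes, and the highest count among the others was 0. Every other split held both cell types on each side, which put the cell type difference into the residual. Low counts there followed from the design, so the splits are no evidence on chance. The number of splits is too small for a share under 0.05.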

How the results depend on the processing

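Restriction to protein-coding genes, centring on olfactory receptor genes and leaving out ribosomal protein genes with their pseudogenes were chosen only after the results were seen. Over all alternatives, 115 counts stayed within 1.5 times their value as reported and 75 did not, and of the 14 lists called for cell type, all kept their direction against other genes. All 20 genes named for cell type stayed called the same way in all settings that held them. Values of lists for cell type kept their side of the threshold 457 times, crossed it upwards 14 times and fell short 18 times. Of these 18, 14 were with an estimated correlation, whose test has 2 degrees of freedom. Lists standing apart on 2 arrays did so again 112 times and not 19 times, and genes named for 2 arrays kept their value within the spread 538 times, moved 10 times and turned 1 time. Another floor or a smaller gene set cannot change a gene's difference between 2 arrays. The mean of the probes changes it only for genes with several probes. Many of the 538 were therefore fixed in advance, and the turn and most of the moves came with quantile normalization. Counts follow as higher and lower where both are given, and the cause was not tested unless stated.

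After quantile normalization 2282 genes were called lower in platelets. The counts of genes at least 1.5-fold apart were 101 lower for CTC41-EVs in platelets, 86 higher between the EV types in platelets, 198 and 46 for CTC41-EVs in progenitors, 293 and 181 for CTC41.5G-EVs in progenitors and 149 lower between the EV types in progenitors. mt-Rnr1 turned to -0.065 for CTC41-EVs in platelets. With arrays scaled to the same median, 2554 genes were called lower in platelets, 343 were higher for CTC41.5G-EVs in progenitors, and 28 and 131 differed between the EV types in progenitors.

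Without a floor, which admits genes near background, the counts in platelets were 604 and 523 for CTC41-EVs, 562 and 493 for CTC41.5G-EVs and 706 and 691 between the EV types. In progenitors they were 131 lower for CTC41-EVs, 965 and 257 for CTC41.5G-EVs and 379 and 215 between the EV types. With the floor at the 90th percentile, which leaves fewer genes, 1430 and 685 genes were called for cell type. In platelets 11 were higher for CTC41-EVs, 24 and 45 for CTC41.5G-EVs, and 16 lower between the EV types. In progenitors 3 were lower for CTC41-EVs, 32 lower for CTC41.5G-EVs, and 30 and 39 between the EV types.

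At a 2-fold threshold, stricter by construction, 1763 genes were called lower in platelets. The counts were 5 and 10, 4 and 7, and 6 and 6 in platelets and 12 and 1, 59 and 6, and 1 and 5 in progenitors, for CTC41-EVs, CTC41.5G-EVs and the EV types against each other. With protein-coding genes only, a smaller set, 2576 genes were called lower in platelets, and the counts in the same order were 7 and 67, 22 and 28, and 139 and 11 in platelets and 59 and 2, 164 and 20, and 20 and 20 in progenitors. With arrays centred on olfactory receptor genes, which lifts platelets by construction, 7615 genes were called higher and 1033 lower in platelets. In platelets 57 were then higher for CTC41-EVs, 201 lower for CTC41.5G-EVs and 154 lower between the EV types. In progenitors 4 were lower for CTC41-EVs, 352 higher for CTC41.5G-EVs, and 16 and 133 differed between the EV types.

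Leaving out each array in turn gave 2929 to 3137 genes called higher and 4333 to 5181 lower in platelets. Shared EV calls ranged from 0 to 3 for CTC41-EVs, 0 to 2 for CTC41.5G-EVs and 0 to 3 between the EV types. Without the PBS array of platelets they were 1, 0 and 2, without that of progenitors 3, 2 and 2, and without the CTC41-EVs array of progenitors 1, 0 and 3. The exact rank sum test of 3 arrays against 3 cannot go below 0.1 and was not reported, and another pseudocount did not apply to values already on a log scale. Signals near background limit what the arrays resolve, as the counts without a floor show.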

Other observations

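The lists of this part, and the choice of Mir872, came only after the results were seen, and so did the comparison of any EV with PBS.

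Pseudogenes of ribosomal proteins had medians of the same sign as the ribosomal protein list in the comparisons given here, and their likeness was not tested. Of 189 tested, 133 were called higher and 4 lower in platelets than in progenitors, with a median of 0.91 (adjusted p = 5.53e-20, and adjusted p = 0.517 with an estimated correlation). On the EV arrays of progenitors, 149 of 161 were above PBS with CTC41-EVs and 142 with CTC41.5G-EVs, with medians of 0.54 and 0.62 (percentile 100 for each). In platelets the medians were -0.30 and -0.11 (percentile 0 for each), whereas the ribosomal protein list did not stand apart with CTC41.5G-EVs (-0.06, percentile 1.16). The probes cannot be assumed to separate pseudogenes from parent genes. Other genes of translation whose messages carry a 5' terminal oligopyrimidine tract had medians of 0.32 (percentile 99.92) and 0.40 (percentile 99.84) on the EV arrays of progenitors, with Pabpc1 at 0.89 and 1.13. In platelets their medians were -0.21 (percentile 16.2) and 0.00 (percentile 21.82). Without a floor the list stood below matched lists in platelets with CTC41-EVs (16 of 17 lower, median -0.28, percentile 0.87) and did not stand apart in progenitors with CTC41.5G-EVs (median 0.26, percentile 98.42). Of 17 such genes, 13 were called higher in platelets than in progenitors (adjusted p = 2.61e-07, and adjusted p = 0.517 with an estimated correlation).

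Of 277 olfactory receptor genes, 241 were called lower in platelets than in progenitors, with a median of -1.12 (adjusted p = 1.36e-16, and adjusted p = 0.385 with an estimated correlation). Of 51 type 1 vomeronasal receptor genes, 47 were called lower, with a median of -2.60 (adjusted p = 1.62e-12, and adjusted p = 0.385 with an estimated correlation). Only members past the floor were tested, and without a floor the medians were -0.65 over 1084 olfactory and -0.72 over 183 vomeronasal genes. Of those tested, 168 olfactory and 41 vomeronasal genes lay below the floor in platelets and 0 of either family in progenitors. Many thus entered through their progenitor signal, which favours calls lower in platelets, so these counts and p-values hold for selected members. Centring arrays on the olfactory genes sets their own shift to 0 by construction. The olfactory family had median signals of 4.14, 4.14 and 4.14 on the platelet arrays and 5.18, 5.27 and 5.33 on the progenitor arrays. Lung epithelium genes, with 2 of 18 called higher and 6 lower, did not pass for cell type (adjusted p = 0.468). This list was made after Sftpc and Scgb1a1 were seen and holds both, so it is not independent evidence. With both EV arrays set against PBS it had a median of 0.13 in platelets (adjusted p = 6.35e-06, and adjusted p = 0.951 with an estimated correlation). In progenitors the median was 0.04 and the test pointed down (adjusted p = 0.775). The difference between the cell types had a median of 0.21 (adjusted p = 4.85e-05, and adjusted p = 0.972 with an estimated correlation). Averaged over both cell types, the median was 0.10 with CTC41-EVs (adjusted p = 0.0816) and 0.13 with CTC41.5G-EVs (adjusted p = 0.0231, and adjusted p = 0.909 with an estimated correlation). Type 1 vomeronasal genes had medians over both cell types of -0.04 with CTC41.5G-EVs (adjusted p = 0.00133, and adjusted p = 0.909 with an estimated correlation) and -0.07 between the EV types (adjusted p = 0.000572, and adjusted p = 0.975 with an estimated correlation). In progenitors their medians over 48 genes were 0.08 with CTC41-EVs (percentile 56.38), -0.13 with CTC41.5G-EVs and -0.21 between the EV types (percentile 0 for each of the last 2). Ribosomal protein pseudogenes had a median over both cell types of 0.24 with CTC41.5G-EVs (adjusted p = 0.0384, and adjusted p = 0.909 with an estimated correlation).

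The model of both EV arrays against PBS has no spread for the lone PBS array, so its p-values here and above do not separate an EV effect from a difference between the PBS pools. With both EV arrays set against PBS in limma, 1 of 18875 genes was called in platelets, the microRNA gene Mir872, with a log2 difference of -1.75 (adjusted p = 0.0341). Its values were 4.85 with PBS, 3.13 with CTC41-EVs and 3.06 with CTC41.5G-EVs, below PBS on 2 of 2 EV arrays, so the call rests on 1 PBS array. All 3 values lay below the floor of 5.07 for comparisons of 2 arrays and both EV values below that of 4.23 for tests, so they are near background. At an unadjusted p under 0.05 were 980 genes, where chance gives 944. In progenitors limma called 0 genes, with 854 at an unadjusted p under 0.05. In platelets ribosomal protein genes had a median of -0.17 (adjusted p = 0.00163), oxidative phosphorylation genes one of -0.14 (adjusted p = 0.00303) and neutrophil genes one of 0.08 (adjusted p = 0.0076). With an estimated correlation the adjusted p was 0.951 for each. In progenitors ribosomal protein genes had a median of 0.45 (adjusted p = 1.45e-10), immediate early genes 0.18 (adjusted p = 5.51e-06), oxidative phosphorylation genes 0.24 (adjusted p = 0.0113), stem and progenitor genes 0.20 (adjusted p = 0.0204) and microRNA genes -0.02 (adjusted p = 3.78e-06). With an estimated correlation the adjusted p was 0.916 for each.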
